A study of Mus musculus with 2 samples.

How the data were processed

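The study measured gene expression by position in epididymal adipose tissue of male C57BL/6J mice, with 1 section from the standard diet and 1 from the high-fat diet, as given by the treatment labels. Per the labels' protocols, paraffin sections were treated with proteinase K, their RNA was transferred to a slide of spatial barcodes with the CytAssist instrument, and libraries followed the supplier's instructions. Per the submitters' processing notes, the authors used Space Ranger 2.0.1 and the mouse build mm10. The deposited matrices hold whole-number UMI counts per gene and spot for the spots that the deposited position tables mark as over tissue, and no normalization had been applied. Other steps upstream of the counts, such as the probe set or the settings of Space Ranger, are not given in the sources used here. The image scale factors were not used.

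Analysis started from these counts. The gene table lists 19465 genes, of which 19084 were matched by symbol to the RefSeq genes of GRCm38.p6, the assembly of mm10, for coordinates. All sums were made over the spots over tissue of a section (2334 lean, 3769 obese), and CPM divides by the section total. Sums have exact Poisson intervals, ratios of the sections exact conditional binomial intervals and shares of spots exact Clopper-Pearson intervals, all at 95% and for counting error only. With 1 section per group no test was possible, and the spread over 4 spatial blocks of each section, divided at the median row and column, is given as a range for the main lists and not as replicates. A UMI was worth 0.109 CPM in the lean and 0.0624 CPM in the obese section, and a count of 0 was read as up to 3 UMIs.

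Before the data were examined, 34 gene lists (456 genes) were fixed for the cell types and processes of obese fat and of the tissues beside it. They covered general, lipid-associated and resident macrophages, fibrillar collagens, collagen VI and basement membrane, matrix remodelling, fibroblasts and progenitors, myofibroblast activation, adipocytes, lipogenesis, insulin signalling, the respiratory chain, thermogenic adipocytes, blood and lymphatic endothelium, smooth muscle and pericytes, B and plasma cells, T and NK cells, dendritic cells, neutrophils, mast cells, mesothelium, epididymis and testis, skeletal muscle, Schwann cells, red blood cells, inflammatory ligands, macrophage to fibroblast signalling, antigen presentation, interferon response, lysosome, hypoxia, proliferation, and immediate early and heat shock genes. Members needed 20 UMIs over both sections. The shift of a list is the median log2 ratio of its members, with the order-statistic interval of the median and its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins. Members at least 1.5-fold apart were counted by size.

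Genes named in the text were chosen by a rule fixed at the same time: the 12 highest and 12 lowest ratios among genes with at least 20 CPM in the higher section and 100 UMIs in all, the 2 most abundant and the 2 most changed members of each list, and Col1a1, Col3a1, Clec4e, Osm, Osmr, Tgfb1, Pdgfra, Adipoq, Lep, Trem2 and Adgre1. Within each section it took the 10 highest and 5 lowest ratios of macrophage-rich spots among genes with at least 50 CPM, and for each region the 5 leading genes by fold with at least 50 CPM, of which the first are named. Clone and model names were skipped. Acp5, as the exception in its list, and Apoa2 and Ttr of the hepatocyte list were named after their values were seen.

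Shares of spots were taken after every spot with at least 1000 UMIs was thinned to 1000 UMIs. The share of spots above the 90th percentile of the lean macrophage share was taken on these thinned counts. Macrophage-rich spots were, among spots with at least 1000 UMIs and without thinning, the 10% of a section's spots with the highest share of UMIs from the general macrophage list, and genes of that list were left out of the lists compared between these and the other spots. Distances are steps on the hexagonal grid, on which a spot has 6 neighbours. Correlations across spots are Spearman correlations of list shares, set against 1000 random pairs of lists. Regions came from log-transformed counts per 10000, the 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5, with the neighbour weighting that Scanpy sets by default. A graph without weights was tried first and replaced by it. Genes needed 10 spots.

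After the hepatocyte transcripts were seen, a list of 25 hepatocyte genes was written down, and UMIs of both sections were compared at the 2276 barcodes under tissue in both. The exchange between the sections was estimated by regressing, over 3475 genes outside that list with more than 500 UMIs in each section, the covariance of the sections at the same barcode, after subtracting the mean of the neighbours, on the variance within each section and a term for shared capture efficiency. It was then subtracted at these barcodes. Without the efficiency term the estimates were 17.7% from lean to obese and 10.6% from obese to lean.

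The comparison of the sections, the lists, the exchange and the macrophage-rich spots were tested on simulated data; regions, distances and correlations were not. With 50 genes changed at each size among 13468, intervals held the true ratio for 90% of genes at 0.5-fold, 100% at 1.5-fold and 2-fold and 94% at 4-fold, and for 95.4% of unchanged genes. Of 200 unchanged lists of 15 genes 1.5% lay above the central 95% of random lists, as did 100% of 200 lists with 8 members at 2-fold. In 10% of simulated obese spots the general macrophage list, which chooses the spots, was raised 4-fold and 200 other genes 2-fold. By that list 99.7% of those spots were found, and the 200 genes had a median log2 of 0.95. Whether a smaller rise of the macrophage list would find them was not tested. Sections displaced by 10 columns gave an exchange of 0.0119% and -0.0340%, and an injected 10% and 5% were estimated as 9.49% and 4.56%.

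Alternatives fixed beforehand were TMM factors, the median of ratios, totals without the 50 most abundant genes, the mean over spots, spot filters, thinning to 1000 UMIs, other UMI minimums for list members, other thinning depths, percentiles, score lists and sizes of the macrophage-rich group, other correlations and other resolutions. Those chosen after seeing the data were totals without the hepatocyte list, the spots with the lowest hepatocyte share, obese spots without lean tissue at their barcode, and subtraction of the exchange at both estimates. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, Matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only. Random draws used seed 1.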

Results

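Gene expression was measured by position in 2 sections of epididymal fat, the visceral adipose depot beside the testis, of male C57BL/6J mice. One section came from the standard diet (lean section) and the other from the high-fat diet (obese section), each kept up for 36 weeks. The series concerns how macrophages and fibroblasts communicate while adipose tissue becomes fibrotic in obesity. The comparisons set the macrophage, fibroblast, matrix and adipocyte genes of both sections side by side. RNA of paraffin sections was moved onto a slide of barcoded spots, and every captured molecule was counted by its unique molecular identifier (UMI). A spot can hold several cells or part of 1 large adipocyte, so spots are described as small regions and not as cells. The lean section had 2334 spots over tissue, 9212351 UMIs in all, and a median of 3607 UMIs and 1856 genes per spot. The obese section had 3769 spots over tissue, 16035252 UMIs, and a median of 3603 UMIs and 1999 genes per spot. With 1 section per diet there is no replicate spread, so no test was made and no p-value is given, and differences compare these 2 sections, not the diets. Intervals of single genes, summed levels and shares of spots are 95% intervals that cover counting error only. Those of list medians are order-statistic intervals over the members of a list, which show the spread between genes and not counting error. Levels are UMIs scaled to the section's total (CPM). Counts of genes at least 1.5-fold apart are counts by size.

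Both sections carried transcripts of hepatocytes, the main cells of liver, which the labels do not name as a tissue of the study. A list of 25 hepatocyte genes, chosen after seeing the data, held 5.32% of the UMIs of the lean and 4.05% of the UMIs of the obese section, with Alb (serum albumin) at 22355 and 17059 CPM, Apoa2 at 6040 and 4625 CPM and Ttr at 4142 and 2984 CPM. None of the 25 genes was in another list (0 shared). That does not show the other lists to be free of liver RNA, which was not tested. A gene typical of liver outside the 25, Serpina1e, stood at 1210 CPM over obese spots with at least 1000 UMIs. At the 2276 spot barcodes that lay under tissue in both sections, the list had a mean of 213 UMIs per spot in the lean and 214 in the obese section, with a Spearman correlation of 0.978 across these barcodes. The correlation was 0.142 against the barcode 10 columns away. Adipose genes matched barcode by barcode too: Cfd, the adipocyte-secreted complement factor adipsin, had a correlation of 0.816 in UMIs per spot against 0.111 for the displaced barcode. In the obese section Cfd stood at 3025 CPM (2992 to 3058) where the lean section had tissue at the same barcode and at 1187 CPM (1158 to 1216) at the 1493 spots where it had none. From 3475 genes the UMIs shared in this way were estimated as 13.1% of the lean signal in the obese section and 8.74% of the obese signal in the lean section. Only the 25 hepatocyte genes were left out of this estimate. RNA of other genes from another library could count as exchange, which was not tested. Levels with this exchange subtracted, and levels of the obese spots without lean tissue at their barcode, are given beside the main gene groups. Both were chosen after seeing the data. Single genes are given as deposited unless stated, and their intervals do not cover the exchange.

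**Figure D1:**
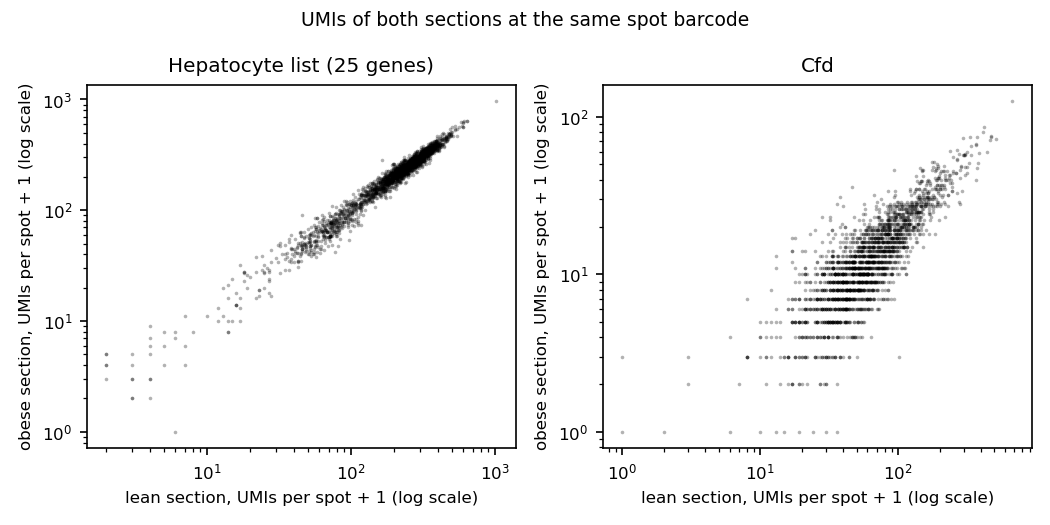
UMIs per spot plus 1 in the lean section (x axis, log scale) and the obese section (y axis, log scale) at the 2276 barcodes under tissue in both sections, 1 point per barcode, for the hepatocyte list (left) and Cfd (right). The points of the hepatocyte list lie along a narrow diagonal (Spearman 0.978), and those of Cfd along a broader one (Spearman 0.816).

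Macrophage genes were higher in the obese section. Of 14 general macrophage genes, 13 were at least 1.5-fold higher and 0 lower, with a median of 2.68-fold (log2 1.42, interval over members 1.02 to 2.01). Ctss, a lysosomal protease of antigen-presenting cells, stood at 159 CPM in the lean and 727 CPM in the obese section (4.56-fold, 4.32 to 4.82). Cd68, a lysosomal glycoprotein of macrophages, stood at 153 and 676 CPM (4.41-fold, 4.17 to 4.66). Adgre1, which encodes the macrophage surface protein F4/80, was 3.17-fold higher (2.67 to 3.80). The list lay at percentile 100 among 10000 random lists of its size and expression, whose median was 0.07. Its median was 1.78 with the exchange subtracted and 1.57 over obese spots without lean tissue at their barcode, and it ranged from 0.81 to 1.70 over pairs of the 4 spatial blocks of each section (block pairs).

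Genes of lipid-associated macrophages, the cells that gather around dying adipocytes and take up their lipid, differed most among the macrophage lists. Of 15 genes, 14 were at least 1.5-fold higher in the obese section, with a median of 5.06-fold (log2 2.34, interval 1.24 to 2.61; percentile 100). Gpnmb, a glycoprotein of lipid-laden macrophages, went from 290 CPM in the lean to 1990 CPM in the obese section (6.87-fold, 6.61 to 7.15). Lgals3, the lectin galectin-3, went from 459 to 2727 CPM (5.94-fold, 5.75 to 6.13). Trem2, the lipid-sensing receptor on chromosome 17 (48346401 to 48352276, mm10) that names this state, was at 35.7 and 206 CPM (5.76-fold, 5.14 to 6.47). Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was 6.30-fold higher (5.62 to 7.08). The member below this size was Acp5, at log2 -0.10. With the exchange subtracted the median was 3.65, and over obese spots without lean tissue at their barcode it was 2.01. Over block pairs it ranged from 0.95 to 3.24. Gpnmb moved from log2 2.78 to 4.92 and 2.51 in these ways, Lgals3 from 2.57 to 3.91 and 2.55, and Trem2 to 3.66 with the exchange subtracted.

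Genes of resident, perivascular macrophages went both ways. Of 11 genes, 2 were at least 1.5-fold higher and 5 lower, and the median was -0.12 (interval -1.35 to 0.72; percentile 4.5). Cd163, the scavenger receptor for haemoglobin complexes, was 2.87-fold lower in the obese section (73.8 against 25.7 CPM, 2.54 to 3.25) and the lectin gene Cd209g 2.55-fold lower (2.25 to 2.90). Mrc1, the mannose receptor, was 1.71-fold higher (1.59 to 1.83), and Gas6, a ligand of the receptor Axl, 1.20-fold (1.14 to 1.27). The median was -0.37 with the exchange subtracted and 0.03 over obese spots without lean tissue at their barcode, where its sign turned. Over block pairs it ranged from -0.90 to 0.44.

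Fibrillar collagen genes were higher in the obese section. Of 7 measured genes 5 were at least 1.5-fold higher and 0 lower, with a median of 1.80-fold (log2 0.85, interval 0.25 to 1.10; percentile 99.86). Col1a1 (chromosome 11, 94936224 to 94953042), a chain of type I collagen, stood at 252 CPM in the lean and 539 CPM in the obese section (2.14-fold, 2.04 to 2.24). Col3a1 (chromosome 1, 45311538 to 45349706), the chain of type III collagen, was at 914 and 1788 CPM (1.96-fold). Col1a2 was 1.80-fold higher (1.74 to 1.86). The median was 1.01 with the exchange subtracted and 0.98 over obese spots without lean tissue at their barcode, and ranged from 0.53 to 1.12 over block pairs. Of 14 genes of collagen VI and basement membrane 5 were higher by this size, among them Col6a3 (2.84-fold, 2.62 to 3.08), Col6a1 (1.79-fold, 1.71 to 1.88) and Sparc, a collagen-binding matrix protein (1.51-fold, 1.49 to 1.54). Col4a1 of basement membranes was 1.41-fold higher (1.36 to 1.45). The list median was 0.39 (interval 0.15 to 0.73; percentile 99.14), 0.35 with the exchange subtracted and 0.56 over the spots without lean tissue.

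Most matrix remodelling genes and the median fibroblast gene were higher in the obese section, with single members that were lower. Of 22 matrix remodelling genes 14 were at least 1.5-fold higher and 2 lower (median log2 0.78, interval 0.22 to 1.13; percentile 100). Their median was 0.96 with the exchange subtracted and 0.88 over obese spots without lean tissue at their barcode. Timp2, an inhibitor of metalloproteinases, was 2.12-fold higher (2.04 to 2.19), Timp1 4.72-fold (2.92 to 8.05, from 19 UMIs in the lean section) and Mmp14, a membrane-bound collagenase, 2.57-fold (2.33 to 2.84). Fn1, fibronectin, was 1.08-fold apart (1.04 to 1.11), a difference that turned to lower with TMM factors (log2 -0.03), with the median of ratios (-0.04) and without the most abundant genes. Of 18 genes of fibroblasts and their progenitors 8 were higher and 1 was lower by this size (median 0.58, interval 0.19 to 1.01; percentile 99.99; block pairs 0.20 to 1.04). With the exchange subtracted 12 were higher and the median was 0.73, and over the spots without lean tissue it was 0.70. The summed level of this list was nearly the same in both sections (7903 and 7952 CPM), with Gsn its largest part. Lum, the collagen-binding proteoglycan lumican, was 4.02-fold higher (3.74 to 4.32), Dpt (dermatopontin) 2.01-fold (1.96 to 2.06), Fbln1 (fibulin) 2.43-fold (1.87 to 3.18) and Pdgfra, the receptor that marks fibroblast progenitors, 2.21-fold (1.92 to 2.56). Gsn, the actin-severing protein gelsolin, was 1.62-fold lower (1.60 to 1.65) at 5123 against 3153 CPM. Genes of myofibroblast activation had a median of 0.40 with an interval across 0 (-0.35 to 1.41). Of 11 members 4 were higher, among them Comp, a cartilage matrix protein (4.51-fold, 3.13 to 6.69), and Cdh11, a fibroblast cadherin (2.66-fold, 1.84 to 3.95), and 1 was lower. The contractile genes Acta2 and Tagln stood at log2 -0.35 and -0.08.

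Among 37 measured ligand and receptor genes of macrophage to fibroblast signalling, 15 were at least 1.5-fold higher in the obese section and 2 lower (median log2 0.38, interval 0.24 to 0.93; percentile 99.95). Their median was 0.45 with the exchange subtracted and 0.47 over obese spots without lean tissue at their barcode. C3ar1, the receptor for complement fragment C3a, was 5.27-fold higher (4.75 to 5.85), Cd44, a receptor for hyaluronan and osteopontin, 3.64-fold (3.40 to 3.91), Tgfb1, the profibrotic growth factor, 2.06-fold (1.88 to 2.25) and Osmr, the oncostatin M receptor, 1.91-fold (1.70 to 2.14). C3 itself was 1.30-fold higher (1.27 to 1.33), and Igf1 was 1.11-fold lower (1.08 to 1.15). The ligand gene Osm had 7 UMIs in the lean and 36 in the obese section (2.95-fold, 1.30 to 7.87). Clec4e, the pattern receptor Mincle of macrophages, had 4 and 8 UMIs, and a difference was not detectable at this depth (1.15-fold, 0.31 to 5.21). Of 16 inflammatory ligand genes 10 were higher and 0 lower (median 1.26, interval 0.17 to 1.93; percentile 100; 1.56 with the exchange subtracted and 1.26 without lean tissue), with Il1rn, the interleukin-1 receptor antagonist, at 5.25-fold (4.44 to 6.24), and the chemokine genes Ccl8 at 2.09-fold (1.83 to 2.39) and Ccl4 at 4.40-fold (1.33 to 22.9, from 3 lean UMIs). Ccl4 turned to lower (log2 -0.28) when spots were thinned to 1000 UMIs.

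Adipocyte genes were lower in the obese section. Of 16 genes 6 were at least 1.5-fold lower and 0 higher, with a median of 1.37-fold lower (log2 -0.46, interval -1.14 to -0.24; percentile 0.01; block pairs -0.62 to -0.30). Cfd was 7.86-fold lower (7.78 to 7.95) at 18890 against 2402 CPM, a log2 ratio of -2.98 that moved to -4.35 with the exchange subtracted and -3.99 over obese spots without lean tissue at their barcode. Other members were lower by less: Retn, the hormone resistin, 2.76-fold (2.67 to 2.84), Car3, a carbonic anhydrase abundant in fat, 2.21-fold (2.20 to 2.22) and Fabp4, the fatty acid carrier of adipocytes, 1.43-fold (1.43 to 1.44). Adipoq, the hormone adiponectin, was 1.31-fold lower (1.29 to 1.34), and Lep, the satiety hormone leptin, was 1.42-fold higher (1.38 to 1.46). The median was -0.69 with the exchange subtracted, where 11 of the 16 genes were lower by this size, and -0.27 over obese spots without lean tissue at their barcode. Of 13 insulin signalling and glucose uptake genes 6 were lower and 1 was higher (median -0.42, interval -1.20 to -0.07; percentile 0.01), led by Pck1, an enzyme of glyceroneogenesis (2.77-fold lower, 2.71 to 2.84). Their median was -0.52 with the exchange subtracted and -0.43 over the spots without lean tissue. Adrb3, the adrenergic receptor of adipocytes, was 2.49-fold lower (2.41 to 2.57).

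Lipogenesis and mitochondrial genes did not shift as groups by this size. Of 16 lipogenesis genes 5 were higher and 3 lower, with a median of 0.23 and an interval of -0.49 to 0.68 (percentile 91.7). The desaturase Scd1 was 1.93-fold lower (1.90 to 1.95) and Acacb, the carboxylase at the mitochondrial surface, 3.22-fold lower (2.98 to 3.48). The desaturase Scd2 was 2.92-fold higher (2.65 to 3.22) and Dgat2, which completes triglycerides, 1.71-fold higher (1.68 to 1.74). All 21 measured respiratory chain genes lay within 1.5-fold (median -0.05, interval -0.17 to -0.01; percentile 22.92), over a range of -0.42 to 0.28. The most abundant, Atp5b and Atp5a1, stood at log2 -0.01 each, and Ndufv1 and Ndufb8 at -0.41 and -0.42.

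Genes of mast cells and neutrophils were higher in the obese section, and genes of blood vessels were not. All 8 mast cell genes were at least 1.5-fold higher (median 5.74-fold, log2 2.52, interval 0.96 to 2.80; percentile 100), with the chymase gene Cma1 at 15.5 and 108 CPM (6.98-fold, 5.88 to 8.34). The carboxypeptidase gene Cpa3 was 6.17-fold higher (4.65 to 8.34) and the tryptase gene Tpsb2 5.40-fold (4.37 to 6.74). The list median was 4.14 with the exchange subtracted and 2.07 over obese spots without lean tissue at their barcode, and ranged from 0.43 to 4.10 over block pairs. The 3 measured neutrophil genes were higher, S100a8 by 3.92-fold (2.93 to 5.34), S100a9 by 5.17-fold (3.03 to 9.49) and Csf3r by 2.10-fold (1.44 to 3.15). Their median was log2 1.97. Blood endothelial genes had a median of 0.02 (interval -0.20 to 0.17; 1 of 12 higher, 1 lower), which turned negative with TMM factors (-0.12) and with the other scalings tried. Rgcc was 2.01-fold lower (1.94 to 2.09), Gpihbp1, which holds lipoprotein lipase on capillaries, stood at log2 -0.20, and Emcn, the glycoprotein endomucin, was 1.78-fold higher (1.56 to 2.04). Smooth muscle and pericyte genes had a median of 0.19 (-0.43 to 0.94), which turned to -0.09 over obese spots without lean tissue at their barcode, with Rgs5 at 0.26 and Mylk at 0.19. Actg2 and Cnn1 were 4.94-fold (3.10 to 8.29) and 1.92-fold (1.36 to 2.74) higher. Both turned to lower over obese spots without lean tissue at their barcode (log2 -0.75 and -1.15), while with the exchange subtracted they stood at 4.65 and 1.93.

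Lists of lymphocytes, dendritic cells and other cell types had intervals across 0, few UMIs or few members. B and plasma cell genes had a median of 0.48 with an interval across 0 (-0.24 to 1.20; 5 of 10 higher, 1 lower), with the immunoglobulin chain genes Ighm at log2 0.81 and Igkc at -0.24, Cd22 at 1.91 and Ms4a1 at -1.27. T and NK cell genes had a median of 0.48 (0.06 to 1.63; 4 of 14 higher, 0 lower), which ranged from -0.43 to 1.49 over block pairs. Il7r, a cytokine receptor of T cells, was 4.71-fold higher (3.59 to 6.29), Trac was 1.45-fold higher (1.02 to 2.09), and Cd8a had 1 and 21 UMIs (12.1-fold, 1.94 to 499). Dendritic cell genes stood at 0.13 (-0.71 to 0.52), a sign that turned with the median of ratios (-0.01) and with the mean over spots (-0.04). Cd209a was 2.12-fold lower (1.64 to 2.74), Clec10a 1.38-fold higher (1.25 to 1.54), Fscn1 at 0.13, and Flt3 had 1 and 26 UMIs. Mesothelial genes stood at -0.40 (-0.70 to 0.09), at 0.60 over obese spots without lean tissue at their barcode and at -1.59 with the exchange subtracted, with Krt8 at -0.49, Wt1 at 1.55 and Muc16 at -1.21. The lymphatic list stood at 0.45 (range 0.01 to 2.40), with Pdpn at 0.84, Prox1 at 0.01 and Mmrn1 at 2.40. Schwann cell genes had a median of -0.48 over 4 members, led by Scn7a at -0.71, with Mbp at 0.53, and red blood cell genes of -0.10, with Hbb-bs at 0.44 and Hba-a2 at -0.23. Of the tissues next to the depot, the epididymis and testis list had 1 measured gene, Insl3 (log2 0.61), and the skeletal muscle list 4 (median 0.26, range -2.91 to 1.81). The summed skeletal muscle list was lower in the obese section (158 CPM lean, 32.6 CPM obese). Its median turned to -0.55 with only members of at least 100 UMIs.

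Over all 13468 genes with at least 20 UMIs the median log2 ratio was 0.17, so a list at 0.17 moved with the average gene. TMM factors put this median at 0.04 and the median of ratios at 0.02. By size, 19.5% of the genes were at least 1.5-fold higher in the obese section and 5.28% lower. The highest ratios included Ubd, a ubiquitin-like modifier induced by inflammatory cytokines (1.95 and 22.9 CPM, log2 3.55, 2.87 to 4.32), the orphan receptor gene Gpr50 (8.52-fold, 5.85 to 12.9), the lipase gene Lipf (6.99-fold, 5.79 to 8.52), the transcription factor gene Egr2 (6.96-fold, 4.69 to 10.7) and Adam8, a metalloproteinase of myeloid cells (6.45-fold, 5.64 to 7.40). Pkib, Lat2, Gnal and the immunoglobulin joining segment Ighj4 lay between 6.19-fold and 6.58-fold, as did Dcstamp, named as a member of the lipid-associated list. The lowest, after Cfd, were Acta1, the actin of skeletal muscle (7.52-fold lower, 6.66 to 8.52), and the immunoglobulin segment Ighj1 (7.36-fold, 6.61 to 8.20; 7.23 to 533 CPM over the 4 blocks of the lean section). They were followed by Mmp9, a gelatinase (5.42-fold, 4.26 to 6.95), the growth factor gene Igf2 (4.19-fold, 3.44 to 5.13), Timp4, the metalloproteinase inhibitor of adipocytes (4.18-fold, 3.97 to 4.41), and Cyp2e1, a cytochrome of fat and liver (4.13-fold, 4.07 to 4.20). Dennd2d, Mycl and Axin2, an inhibitor of Wnt signalling, were 3.91-fold, 3.13-fold and 3.06-fold lower.

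**Figure D2:**
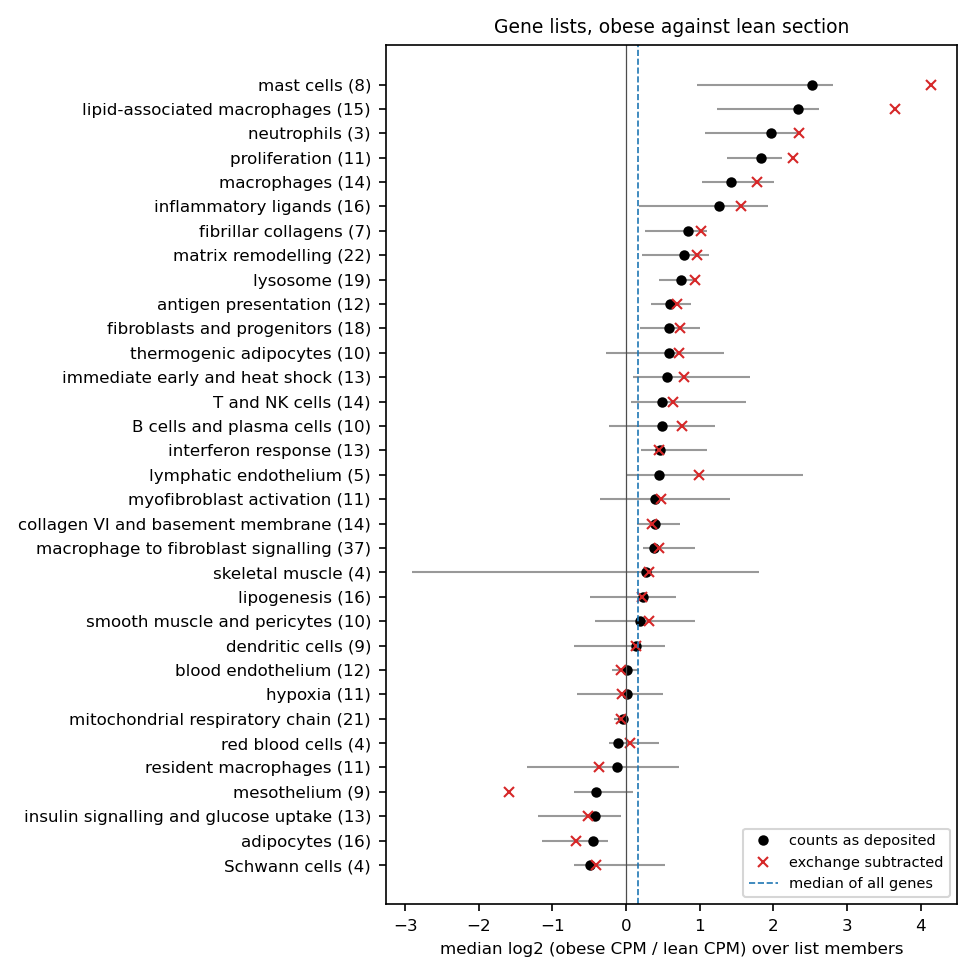
Median log2 ratio of obese over lean CPM over the members of each gene list (x axis). The number of measured members follows each name. Black points are counts as deposited. Grey bars are the order-statistic interval of the median (the range for lists of under 6 members). Red crosses are the values with the exchange subtracted, over the shared barcodes only. The dashed line is the median of all genes (0.17). Mast cells (2.52) and lipid-associated macrophages (2.34) lie at the top and adipocytes (-0.46) near the bottom; the signs of blood endothelium, hypoxia and dendritic cells turned under other scalings.

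Spots with collagen and macrophage transcripts were more frequent in the obese section once each spot was thinned to 1000 UMIs, which left out 38 lean and 47 obese spots. Col1a1 was found in 20.3% of lean spots (18.6 to 22.0, exact Clopper-Pearson interval) and 34.8% of obese spots (33.3 to 36.3), against 49.9% and 66.8% without thinning. Col3a1 was found in 50.4% and 67.6% of spots, Trem2 in 3.14% (2.46 to 3.93) and 14.5% (13.3 to 15.6), Gpnmb in 16.4% and 52.8%, and Cma1 in 1.44% and 6.61%. Adipoq was found in 91.9% of lean and 85.2% of obese spots and Cd163 in 6.05% (5.11 to 7.11) and 2.55% (2.07 to 3.11). Osm was found in 0 of 2296 lean spots (limit 0.161%) and 0.161% of obese spots (0.0592 to 0.351) and Clec4e in 0.0436% and 0.0269%, against at most 0.131% for genes of other tissues (Ckm, Myh4, Prm1, Lcn5 and Sox10). Without thinning Osm was found in 0.2999% of lean and 0.902% of obese spots (0.626 to 1.26) and Clec4e in 0.171% and 0.212%, against at most 0.214% for these genes. Spots above the 90th percentile of the lean macrophage share (over 4 of 1000 UMIs) made up 33.9% of obese spots (32.4 to 35.5) and 6.14% of lean spots (5.19 to 7.20); 1170 obese spots lay within 1 UMI of this limit.

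**Figure D3:**
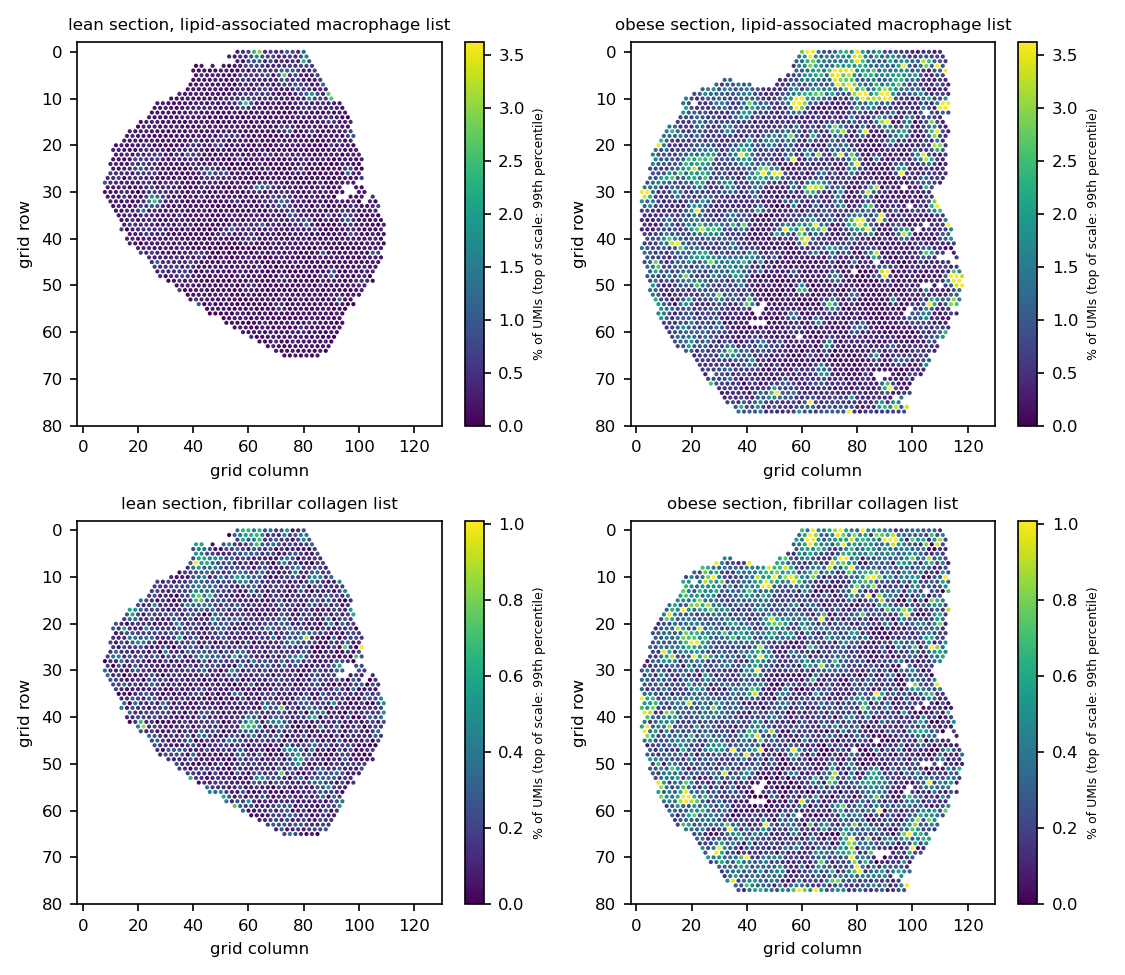
Position of every spot over tissue with at least 1000 UMIs (grid column and row) in the lean (left) and obese (right) section, coloured by the percent of its UMIs from the lipid-associated macrophage list (top) or the fibrillar collagen list (bottom), on 1 colour scale per list that ends at the 99th percentile. The obese section shows scattered patches of high lipid-associated macrophage share, and its list CPM was 11148 against 3150 in the lean section.

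Within the obese section, the tenth of spots with the highest macrophage share comprised 372 of 3722 spots with at least 1000 UMIs. Their share of UMIs was higher for lipid-associated macrophage and lysosomal genes and lower for adipocyte genes. These spots had more UMIs than the others (median 5788 against 3466.5), and 32.3% of their neighbours were also macrophage-rich, against 7.48% of the neighbours of other spots. Of 15 lipid-associated genes 14 were at least 1.5-fold higher there (median log2 1.45, interval 1.06 to 1.74; percentile 100). Apart from the macrophage list used to choose the spots, the highest ratios were those of Adam8 (3.96-fold, 444 against 112 CPM), the myeloid regulator Arhgap25 (3.84-fold), Mmp12, the elastase of macrophages (3.82-fold), Gpnmb (3.66-fold), Pirb, Rgs1, Trem2 (3.40-fold), Il1rn, Itgax, the integrin chain of tissue macrophages around dead adipocytes, and C3ar1 (3.33-fold). As shares of UMIs, adipocyte genes were lower (13 of 16 by at least 1.5-fold, median -0.75, interval -0.84 to -0.60), as were insulin signalling genes (8 of 13, -0.75), lipogenesis genes (11 of 16, -0.72) and genes of blood endothelium (5 of 12, -0.56). The summed adipocyte list did not have fewer UMIs per spot there, with 122915 UMIs over 372 spots. At distances of 1, 2 and 3 or more it had 300932 over 1025, 292576 over 1037 and 330007 over 1288 spots. The lowest ratios were those of genes typical of liver (Cth, Hao1, Cyp2c23, Serpina1e and Haao, 2.84-fold to 3.59-fold lower).

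Fibrillar collagens as a list were not higher in the macrophage-rich spots of the obese section by this size, although Col1a1 and Col3a1 were. The median was 0.10 with an interval across 0 (-0.07 to 0.68; percentile 79.87), and 2 of 7 genes were at least 1.5-fold higher, Col1a1 (log2 0.68, 0.61 to 0.76) and Col3a1 (0.67, 0.63 to 0.71). The median of fibroblast genes was 0.05 (-0.56 to 0.22), which turned to -0.16 with the lipid-associated list as score and -0.25 with the exchange subtracted. That of matrix remodelling genes was 0.06 (-0.40 to 0.33), which turned negative over spots of low hepatocyte share, and that of the macrophage to fibroblast signalling genes 0.17 (0.02 to 0.40; 10 of 36 higher, 2 lower), which turned to -0.0088 with the lipid-associated list as score and -0.014 over spots of low hepatocyte share, with Tgfb1 at 1.10 (0.97 to 1.23), Pdgfra at 0.16 (-0.09 to 0.41) and Osmr at -0.03 (-0.26 to 0.19). Resident macrophage genes stood at -0.13 (-1.04 to 0.78), without a stable sign, as they were at -0.71 with the lipid-associated list as score and at 0.41 over spots without lean tissue at their barcode. Across spots, the share of UMIs from macrophage genes and that from fibrillar collagens had a Spearman correlation of 0.34 in the obese section (percentile 98.2 among 1000 random pairs of lists) and 0.20 in the lean section (percentile 99.5), and 0.17 and 0.15 with the adipocyte share and total UMIs held fixed. Spots are not independent samples, so these correlations carry no p-value. The macrophage share also followed that of lipid-associated genes (0.71 in the obese and 0.30 in the lean section) and opposed that of adipocyte genes (-0.30 and -0.21).

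In the lean section, the 230 macrophage-rich of 2296 spots were rich in lipid-associated and resident macrophage genes. The resident genes were not higher when the lipid-associated list chose the spots, a setting that gives no value for the lipid-associated list itself. Lipid-associated genes were higher (10 of 14 by at least 1.5-fold, median 1.27, interval 0.42 to 1.85) and so were resident macrophage genes (9 of 11, 0.92, interval 0.31 to 1.15), whose median turned to -0.094 with the lipid-associated list as score. Fibrillar collagens had a median of 0.44 with an interval across 0 (-0.18 to 0.62; 1 of 7 higher). Mmp12 (4.67-fold, 1020 against 218 CPM), Gpnmb (4.05-fold), Cd44 (3.01-fold), the lectin gene Fcna (2.96-fold) and the protease gene Ctsk (2.93-fold) had the highest ratios, followed by Cyth4, Lgals3, Ccl9, Cybb and C5ar1, and Tmem143, Uri1, Wdr45, Apoc2 and Gcgr the lowest (1.73-fold to 2.22-fold lower). With the exchange subtracted at each shared barcode the lipid-associated median was 0.74 and the resident median 1.12. Over the whole lean section Mmp12 stood at 301 CPM where the obese section had tissue at the barcode and at 78.6 CPM (41.8 to 134) at the 58 spots where it had none, and Gpnmb at 292 and 139 CPM (88.1 to 209). Of the 225 lean macrophage-rich positions that both sections covered, 39.6% (33.1 to 46.3) were macrophage-rich in the obese section too, where 8.31% of positions were; 89 positions were shared against 18.7 for independent positions.

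The summed levels of lipid-associated and mast cell genes declined with distance from macrophage-rich spots in the obese section, and those of fibrillar collagens, mostly carried by 3 genes, fell up to a distance of 2. The lipid-associated list stood at 24388 CPM (24194 to 24583) in these spots, 12306 in adjacent spots, 7835 at a distance of 2 and 6148 (6078 to 6218) at 3 or more. Fibrillar collagens stood at 4795 (4709 to 4882), 3677, 3072 and 3112 CPM (3062 to 3162). Their sum came mostly from Col3a1, Col1a2 and Col1a1 (1788, 824 and 539 of 3520 CPM over the section), and the median gene of the list was not 1.5-fold higher in macrophage-rich spots. Mast cell genes stood at 583 (553 to 614), 320, 230 and 184 CPM (172 to 196). The summed level of collagen VI and basement membrane genes was lower in macrophage-rich spots, at 6723 CPM against 7968, 8148 and 8118. Against all other spots, 0 of their 14 members were 1.5-fold lower, and the median log2 of -0.31 had an interval across 0 (-0.41 to 0.15). Fibroblast genes were at 7188, 7988, 8365 and 7970 CPM and adipocyte genes at 49719, 65683, 71264 and 68194 CPM, both highest at a distance of 2. In the lean section fibrillar collagens stood at 2502 CPM (2400 to 2607), 1944, 1652 (1603 to 1702) and 1790 (1744 to 1837). Their log2 ratio of adjacent over distant spots turned to -0.072 with the lipid-associated list as score.

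**Figure D4:**
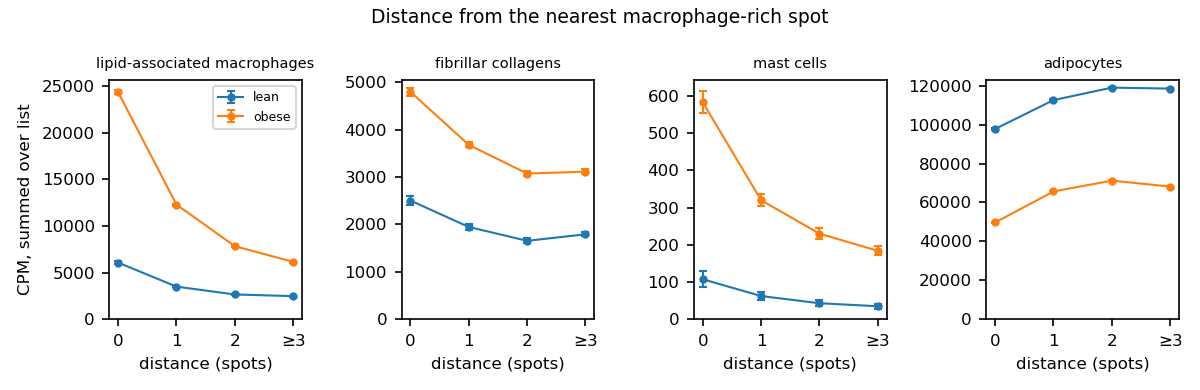
Summed CPM of 4 gene lists (y axis) against the grid distance in spots from the nearest macrophage-rich spot (x axis) in the lean (blue) and obese (orange) section; bars are exact Poisson 95% intervals. The lipid-associated list of the obese section declined from 24388 to 6148 CPM, and its fibrillar collagens, mostly Col3a1, Col1a2 and Col1a1, stood at 4795 CPM in macrophage-rich spots and 3112 CPM at 3 or more.

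Grouping the spots of both sections together by expression gave 7 regions, in 5 of which under 5% of the spots came from the other section, so most regions followed the section and their sizes are not compared between diets. Regions held mainly by the obese section were led by Igha, Selenbp2 and Cyp7b1 (1641 spots), by Adam8, Il1rn and Zranb3, with Lair1 and Lgals3 behind (1191 spots), by Iglc1, Vsig8 and Gpnmb, with Mamdc2 and Sema4d behind (482 spots), and by Slpi, Lipf and Arxes1 (413 spots). Regions held mainly by the lean section were led by Cfd, Cyp2e1 and Acta1 (1598 spots) and by Ighj1, Ighj4 and Acta1 (541 spots). A region of 118 lean and 34 obese spots was led by Actg2, Cldn11 and Cnn1, with 16 of its Actg2 UMIs in the lean and 157 in the obese spots. In obese spots, the region led by Iglc1 and Gpnmb held 18441 CPM of lipid-associated macrophage genes and 4187 CPM of fibrillar collagens, and that led by Adam8 and Il1rn 14709 and 4345 CPM. The region led by Igha stood at 5811 and 2570 CPM. Over its spots of both sections it held the most hepatocyte transcripts (67681 CPM), near the 62825 CPM of the region led by Cfd. The regions led by Iglc1 and Adam8 held 36560 and 14228 CPM of them.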

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

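The test of molecules carried with their barcodes, the barcode match used against RNA spread from outside, the endothelial comparison, the bound used for depth and the subtraction of the exchange were chosen only after the results were seen. The other tests of the hepatocyte transcripts were set after the levels of the most abundant of these genes had been seen, and those of the macrophage genes before their levels were.

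Transcripts of hepatocytes were found in both sections, although the labels name no liver, and drew attention as a signal outside the main measurement. The 25 genes held 5.32% of lean and 4.05% of obese UMIs, and their UMIs matched barcode by barcode between the sections (Spearman 0.978). A piece of liver inside the sections was argued against, since the tenth of spots with most of these UMIs held at most 22.7% of them. Their spread was uneven, with a mean of 214 per obese spot with lean tissue at its barcode and 109 without. Against RNA spread over the tissue from outside stood the match of single barcodes in UMIs, which stayed at 0.899 after the neighbouring spots were subtracted. A capture efficiency shared by a barcode could give part of it, since all other genes matched at 0.68 in the same way. As a share of UMIs the hepatocyte match was 0.73, and 0.58 after subtracting neighbours. These values do not exclude RNA from outside. The slope test planned for it was undecided (1.05 in the lean and 0.29 in the obese section). The genes stood in nearly the same ratios in both sections (SD of their log2 ratios 0.12), as 1 source would give, and Cfd in the obese section was 2.55-fold higher where the lean section had tissue at the barcode, so a candidate explanation is that molecules passed between libraries together with their spot barcodes, with a liver library handled alongside as a candidate source that was not tested.

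Macrophage genes were higher in the obese section (median log2 1.42). A lower share of adipocyte RNA would raise the genes of other stromal cells alike, but blood endothelium stood at 0.015 with an interval apart from that of macrophages; the bound set beforehand was not met, because mast cell genes (2.52) exceeded the macrophage list and lymphatic endothelium (0.45) lay within 1 of it. For depth, the median after thinning was 1.07 (0.77 to 1.75), and the change of -0.35 was above the 0.2 set beforehand. Thinning also gave every spot the same weight, and macrophage-rich obese spots held more UMIs than the others (median 5788 against 3466.5). Median UMIs per spot were alike in both sections (3607 lean and 3603 obese). Thinning keeps the expected share of each gene within a spot, so it could not test depth as a cause of the macrophage shift. The change may reflect the equal weight of spots, the spots left out or the random draw, which were not told apart. Over all genes the median was 0.146 after thinning and 0.145 as the unthinned mean over spots, against 0.168 in the main setting. An exchange between the 2 sections brings their ratio toward 1, so its subtraction widens a difference by calculation. The median of 1.78 after it was also taken over the shared barcodes only, and decides nothing. Carry-over from another library stays open. Differences between diets, animals, sections and libraries cannot be told apart with 1 section per diet, so an effect of the diet stays open and untested.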

How the results depend on the processing

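No paired analysis was possible because each diet has 1 section and no result comes from a test. A list median counted as called when its order-statistic interval left out 0 and it had at least 6 members (a minimum set after seeing the data), and a gene when it was at least 1.5-fold apart; alternatives that use the spots without the other section's tissue, the hepatocyte share or the exchange were chosen after seeing the data. Under these no list median called between the sections changed its direction (0 reversed). The 306 planned and 170 added values cover all 34 lists, and values of lists not called could not count as reversed. Of called single genes 3 changed direction: Actg2 (log2 -0.75) and Cnn1 (-1.15) over obese spots without lean tissue at their barcode, and Ccl4 (-0.28) with spots thinned to 1000 UMIs, from 3 lean UMIs. Of lists not called, resident macrophages, endothelium, smooth muscle, dendritic cells, mesothelium, skeletal muscle, red blood cells and hypoxia changed sign under at least 1 alternative. The macrophage median ranged from 1.07 to 1.90, fibrillar collagens from 0.70 to 1.08, matrix remodelling from 0.64 to 1.02, fibroblasts from 0.43 to 0.78 and adipocytes from -0.74 to -0.27. The lipid-associated median moved to 3.65 and 4.13 with the exchange subtracted at the lower and higher estimate. The obese minus lean share of spots was 14.5 points for Col1a1 and 7.70 and 20.1 points at 500 and 2000 UMIs; for Trem2 it was 11.3 points, and 5.85, 18.9 and 26.6 points at 500 UMIs, at 2000 UMIs and without thinning, since deeper spots show more genes. The share of obese spots above the lean percentile was 30.2% at 500 UMIs, 46.9% at 2000 UMIs, 25.6% at the 95th percentile, 50.4% with the lipid-associated list and 37.9% without lean tissue at the barcode. For macrophage-rich spots of the obese section, the adipocyte median was -0.92 for the top 5%, -0.60 for the top 20% and -0.89 for the spots with the lowest hepatocyte share. The log2 ratio of adjacent over distant spots for lipid-associated genes (1.001) was 0.91 for the top 5% and the top 20%, 1.17 with a thinned score, 0.95 at low hepatocyte share, 0.83 without lean tissue at the barcode and 1.07 with the exchange subtracted. The same ratio for fibrillar collagens (0.24) was 0.28 for the top 20%, 0.14 with the lipid-associated score, 0.31 as a mean over spots, 0.12 at low hepatocyte share, 0.16 without lean tissue at the barcode and 0.19 with the exchange subtracted. That of adipocytes turned to 0.094 for the top 20% and 0.0066 with the lipid-associated score. Between macrophage-rich and other obese spots, the median of signalling genes turned to -0.0088 with the lipid-associated score and -0.014 at low hepatocyte share, smooth muscle to 0.021 without lean tissue at the barcode and mesothelium to 0.20 with the exchange subtracted. In the lean section, resident macrophages turned to -0.094, the adjacent over distant ratio of fibrillar collagens to -0.072 and that of adipocytes to 0.0028, all with the lipid-associated score, and myofibroblast genes to -0.12 at low hepatocyte share; as a score the lipid-associated list gives no value of its own. The correlation of macrophage and collagen shares was 0.31 (Pearson), 0.23 (thinned), 0.17 (partial), 0.33 (at least 2000 UMIs) and 0.27 (without lean tissue) in the obese section, and 0.12 (thinned), 0.15 (partial) and 0.21 (at least 2000 UMIs) in the lean. Regions numbered 13 at the higher resolution and 5 at 0.3, and 5 in the lean and 6 in the obese section when each was grouped by itself. Apart from the thinned shares, the cause was not tested. Depth limits genes of few UMIs, such as Osm and Clec4e.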

Other observations

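The mast cell and proliferation hypotheses were put forward after these genes had been seen to be higher in the obese section, and their tests were set before macrophage-rich spots were examined. That all alternatives must agree in these tests was decided after the values had been seen.

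Lysosomal and antigen presentation genes were higher in the obese section. Of 19 lysosomal genes 12 were at least 1.5-fold higher and 0 lower (median log2 0.74, interval 0.45 to 0.96; percentile 100), among them the proteases Ctsb (2029 and 4122 CPM, 2.03-fold) and Ctsl (1.68-fold), Hexa, a hexosaminidase chain (2.18-fold), and Gla, the galactosidase lacking in Fabry disease (3.79-fold, 3.15 to 4.60). In macrophage-rich spots of the obese section 11 of the 19 were higher (median 0.78). Of 12 antigen presentation genes 7 were higher (median 0.60, interval 0.34 to 0.88; percentile 99.9), with the class II genes H2-DMb1 (3.12-fold, 2.78 to 3.52), Ciita, their master regulator (2.19-fold, 1.70 to 2.86) and Cd74, the invariant chain (1.51-fold, 1.47 to 1.54), while B2m stood at 1.41-fold. Interferon response genes had a median of 0.46 (0.21 to 1.10; 4 of 13 higher, percentile 96.46), with Oas1a (2.59-fold, 1.89 to 3.61) and Rsad2 (2.32-fold) above Bst2 (1.26-fold).

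Immediate early genes and some genes of thermogenic fat were higher in the obese section. Of 13 immediate early and heat shock genes 6 were higher (median 0.56, interval 0.10 to 1.67; percentile 99.84), led by the transcription factors Atf3 (35.0 and 206 CPM, 5.89-fold, 5.25 to 6.62), Fos (3.36-fold, 2.82 to 4.02) and Egr1 (3.19-fold, 2.90 to 3.53). Of 10 thermogenic genes 5 were higher (median 0.58, interval -0.27 to 1.33), with Cox8b (2.65-fold, 2.24 to 3.15) and Dio2 (2.51-fold, 1.15 to 6.27, from 8 lean UMIs) against Ppara at log2 -0.39. Hypoxia genes had a median of 0.01 (-0.67 to 0.50), which turned negative with TMM factors (-0.12). Among them Vegfa, the endothelial growth factor, was 1.62-fold lower (1.52 to 1.73), Bnip3 1.53-fold lower (1.44 to 1.62), Pfkfb3 1.28-fold lower, and Car9 2.70-fold higher from 10 lean UMIs.

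All 11 measured proliferation genes were at least 1.5-fold higher in the obese section (median log2 1.82, interval 1.37 to 2.11; percentile 100), with Mki67, the marker of cycling cells, at 9.44 and 35.4 CPM (3.74-fold, 2.98 to 4.75), Cdk1 at 3.48-fold (2.75 to 4.46), Birc5 at 4.96-fold (3.08 to 8.45) and Ccnb2 at 4.33-fold (2.52 to 7.99). It was hypothesised that the proliferating cells lie in macrophage-rich spots, with a shift there above 1 expected and a shift under 0.3 if not. The shift was 0.87 (0.74 to 1.15), with 11 of 11 genes higher, 1.02 with the exchange subtracted and 0.59 over spots without lean tissue at their barcode, so the hypothesis stays undecided.

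Whether mast cells lie in macrophage-rich spots was not settled. The hypothesis predicted a shift above 1 in the obese section. The shift was 1.29 and rose to 1.45 with the exchange subtracted, but was 0.82 over spots without lean tissue at their barcode and also 0.82 with a score from thinned counts. In all spots it came with 6 of 8 genes at least 1.5-fold higher, among them Cpa3 (log2 1.34, 1.08 to 1.60), Cma1 (1.31, 1.16 to 1.46) and Tpsb2 (1.28, 1.07 to 1.48). The order-statistic interval of the median reached from -0.13 to 1.49, so some members did not follow. The tests written for fibrillar collagens in macrophage-rich spots were not run, because the list was not higher there (median 0.10).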
